A study of Homo sapiens with 52 samples.

How the data were processed

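Total RNA from 18 established human ovarian cancer cell lines was amplified to biotin-labelled cDNA and hybridised to single-colour arrays, 1 array per sample, per the labels. The 52 arrays comprise 3 arrays for each of 17 lines and 1 array for UWB1.289. The labels do not say whether replicates A to C came from separate cultures, so p-values measure the spread between these arrays, which may be technical. They give no batch or scan date.

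The deposited values are log2 probe set intensities made with RMA in the affy package, per the submitters' processing notes; versions, settings and the array's genome build are not given in the sources used here. The labels name no unit, and log2 is the scale that RMA gives. Values ran from 0.93 to 15.53, with array medians between 4.77 and 4.88 and 0 missing values. RMA values near the lower end are close to background and no detection call accompanies them, so differences of dim genes are understated. For arrays, the number of arrays limits the precision.

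Of 120373 probe sets, 83677 carry 1 gene symbol in the platform annotation, 2850 carry several and 33846 are unnamed here. Symbols were updated through the RefSeq gene table of assembly GRCh38.p14, which was also used for the order of neighbouring genes; 18679 of 18762 symbols matched a current symbol and 2393 were updated. The match of values to annotation was checked on pairs of probe sets of the same gene, kept only where both varied among the lines. Their median correlation over line means was 0.968 over 3260 pairs, against 0.0198 after a shift of the annotation by 1 row. Each gene was represented by its probe set with the highest mean over the 52 arrays among probe sets with a single symbol, which gave 18732 genes. Genes above the 25th percentile of all values (3.00 log2 units) in at least 3 arrays were tested, 17576 in all. The brightest probe set is not always the most responsive one; disagreement is given for PAX8, ESR1 and BRCA1, and probe sets of most genes were not compared one by one. Some genes on the preset lists were not analysed here: 406 of 433 were measured.

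Groups are the cell lines named in the labels. For histotypes, labels with serous alone were taken as serous, both clear cell labels as clear cell, and a mixed label or a label without histotype as other. PEO1 with PEO4, UWB1.289 with UWB1.289+BRCA1, and OVCAR8 with NCI/ADR-RES are known to share a donor, from background knowledge and not from the labels. Arrays were averaged per line and these lines per donor, which left 15 donors, 5 serous, 2 clear cell, 2 endometrioid and 6 other.

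Line differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes) in one model of all 52 arrays, which gives 34 residual degrees of freedom and lends the lone UWB1.289 array the spread of the other lines. Histotypes were tested with limma on the 15 donor means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1; for the F test over lines, the range of line means had to reach 1. The 23 gene lists were fixed before the data were examined, as were the tests of the comparisons, the rule for named genes and the alternatives, except omission of PEO1 replicate B from the gene lists and from results other than PEO4 minus PEO1. That omission, and the tests of replicate B against other lines and random lists, were chosen after its deviation was seen. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. Scores are means over a list of gene-centred log2 values. Class differences in scores and correlations used exact permutation tests, and the correlation of scores over 15 donors used 100000 permutations. A gene was restricted to a donor when it exceeded every other donor by at least 2 log2 units with an adjusted p under 0.05 in every contrast.

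The named genes are, for each line pair, the 8 called genes with the largest rise and the 8 with the largest fall, with up to 4 called members of each list discussed. For histotypes they are up to 8 called genes each way, or the 5 with the smallest p each way where fewer than 8 were called. The 2 genes with the largest margin were named per donor. Key genes fixed beforehand were added, and genes known only by a locus or reading frame number were passed over.

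On data simulated from the real genes' means and spreads, with 50 changed genes per size among 17576, the test of PEO4 against PEO1 recovered 100% of changes of 1.5 log2 units and that of UWB1.289+BRCA1 against UWB1.289 recovered 92%. The simulated test of clear cell against serous donors recovered 52% at 1.5 and 96% at 4 log2 units. Changes of all sizes were planted at once, with the same spread in each class and in each line. The real PEO1 arrays varied more than those of other lines, so recovery for that pair may be overstated. Many true changes ease the Benjamini-Hochberg adjustment, so recovery would be lower where few genes differ. Alternatives covered normalization, the probe set rule, the filter on dim genes, the variance model, array weights, a replicate block, the merging of lines by donor, other scores and omission of single arrays or donors. Figures were drawn with matplotlib 3.10.9.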

Results

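Expression was profiled in 18 ovarian cancer cell lines on 52 arrays. Labels call 7 lines serous, 2 clear cell (ES-2 and TOV-21G) and 2 endometrioid (COV362 and TOV-112D); the other 7 carry a mixed label or none of these classes. Replicate arrays of a line correlated at a median r of 0.992 over 51 pairs, computed across probe sets, which are not independent replicates. Arrays of different lines correlated at a median of 0.931. No pair of arrays was identical. PEO1 replicate B stood apart: its residual SD was 0.439 log2 units, against 0.298 for replicate A, 0.247 for replicate C and 0.193 for the next array, COV318 replicate C. Residuals are taken from the mean of the line, so replicate B also widens those of replicates A and C. Those 2 arrays correlated at 0.990 with each other, and at 0.966 and 0.969 with replicate B.

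The first comparison asked how much of the transcriptome separates the lines. PAX8, a transcription factor of Müllerian epithelium, was at 11.48 ± 0.13 log2 units (SD, n = 3) in OVCAR3 and at 9.34 or more in 15 lines, but at 6.46 ± 0.12 in OVCAR5, 4.65 ± 0.14 in ES-2 and 3.95 ± 0.19 in TOV-112D (n = 3 each). Of 21 PAX8 probe sets, 17 were lower in OVCAR5 than in OVCAR3 by 1 log2 unit or more. Among the others, 1 was at 8.37 in OVCAR5, against 8.68 in OVCAR3, 4.54 in ES-2 and 4.01 in TOV-112D. WT1, a marker of serous carcinoma, was highest in PEO4 at 11.05 ± 0.10, followed by PEO1 at 9.22 ± 0.88, OVCAR3 at 8.11 ± 0.14 and OV56 at 7.29 ± 0.21. E-cadherin (CDH1) ranged from 4.05 ± 0.31 in ES-2 to 13.25 ± 0.05 in OVCAR5. Vimentin (VIM), a mesenchymal filament protein, ranged from 5.98 ± 0.26 in OVCAR3 to 13.37 ± 0.05 in TOV-112D. The brightest ESR1 probe set ranged only from 5.34 to 6.13, while another ESR1 probe set reached 10.03 in PEO1, 9.58 in PEO4 and 8.21 in SK-OV-3 and was at 1.80 in TOV-21G, so the probe sets of the oestrogen receptor gene disagree. By the limma F test, 13053 of 17576 genes (74.3%) differed among the 18 lines. The range of 1 log2 unit sets this count, since 13077 genes reached it with or without the test.

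Lines known to share a donor were compared next with all other lines. NCI/ADR-RES and OVCAR8 correlated at r = 0.779 across gene-centred line means, UWB1.289 and UWB1.289+BRCA1 at 0.596, and PEO1 and PEO4 at 0.556. These are ranks 1 to 3 among all line pairs, and in all 3 pairs each line was the other's nearest. The next pair, COV504 (serous) and COV362 (endometrioid), reached 0.273. These correlations are across genes, which are not independent replicates, and no test was made.

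**Figure D1:**
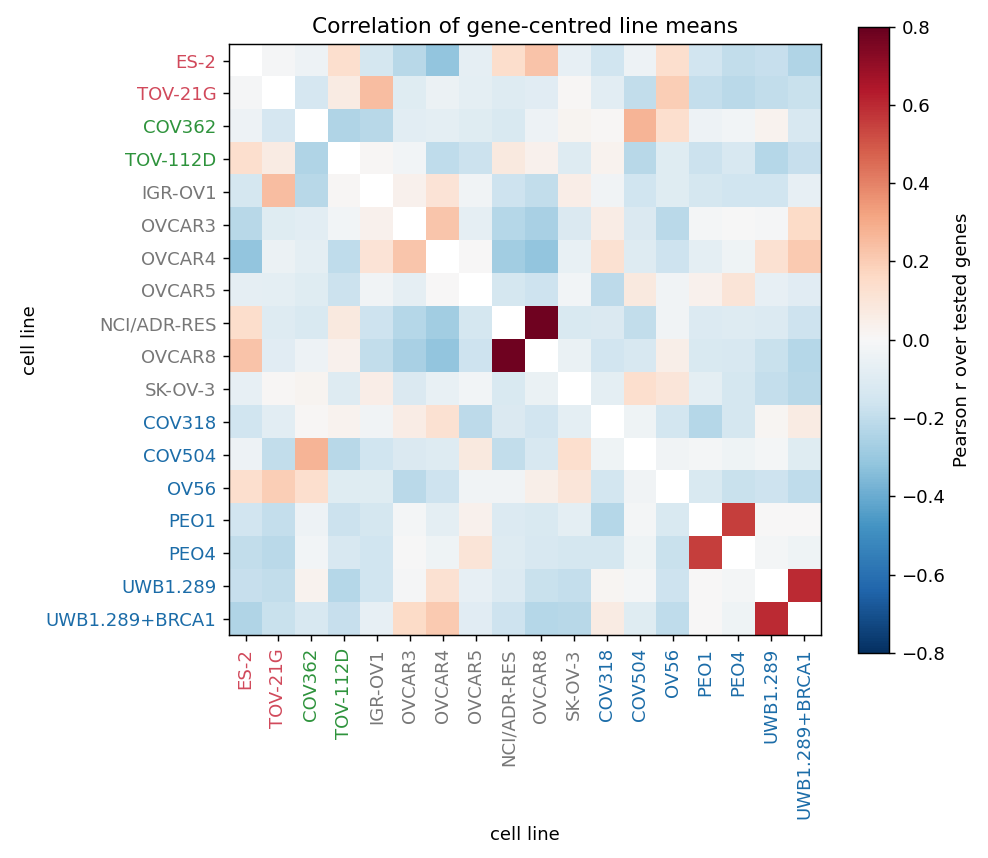
Pearson r between the gene-centred log2 means of the 18 lines over the tested genes, with line names coloured by histotype label (blue serous, red clear cell, green endometrioid, grey other) and the diagonal left white. The 3 pairs that share a donor have r of 0.556 to 0.779, and the next pair has 0.273.

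PEO1 and PEO4 come from the same patient, PEO4 after platinum resistance, as is known of these lines. Interferon-stimulated genes were higher in PEO4. IFIT2 rose by 6.40 ± 0.27 log2 units (SE from the model of all arrays, n = 3 arrays per line). OASL rose by 6.16 ± 0.29, IFIT1 by 5.88 ± 0.24 and IFI44 by 5.65 ± 0.18. These SEs pool the spread of all lines and do not show the spread within PEO1. SDs over the PEO1 arrays were 0.87 for IFIT2, 0.67 for OASL, 0.80 for IFIT1 and 0.34 for IFI44. The PEO4 arrays had SDs of 0.03, 0.07, 0.03 and 0.18 for the same genes. AKR1D1, a steroid reductase, rose by 8.22 ± 0.19, the Wnt ligand WNT11 by 6.37 ± 0.20, the secreted chaperone CLU by 5.95 ± 0.13 and CEP15 by 5.85 ± 0.22. PROM1, which encodes the surface antigen CD133, fell by 8.99 ± 0.28 from 11.99 ± 0.35 (SD) in PEO1, the sphingosine phosphate receptor S1PR1 by 7.14 ± 0.26, BEX1 by 6.86 ± 0.20 and DIRAS3 by 6.26 ± 0.21. The epithelial transcription factor EHF fell by 5.74 ± 0.16, the inhibin subunit INHBB by 5.60 ± 0.19, the oxytocin receptor OXTR by 5.44 ± 0.15 and the growth factor PDGFA by 5.37 ± 0.18.

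Of 32 interferon-stimulated genes, 23 rose in PEO4 and 0 fell, the same counts when adjusted over the list alone (camera adjusted p = 3.2e-24, and adjusted p = 1.9e-06 with an estimated correlation). Among 18 antigen presentation genes 4 rose and 0 fell, both over all genes and adjusted over the list alone, including HLA-F by 2.05 ± 0.23 and the proteasome subunit PSMB9 by 1.76 ± 0.13 (adjusted p = 0.0065, and adjusted p = 0.012 with an estimated correlation). Of 20 inflammatory and NF-kB genes, 6 fell and 1 rose, also adjusted over the list alone; CXCL1 fell by 3.07 ± 0.18 and CXCL8 by 2.61 ± 0.16 (adjusted p = 0.0059, but adjusted p = 0.174 with an estimated correlation). Of 19 hypoxia and glycolysis genes 6 rose and 1 fell, with the same counts adjusted over the list alone; P4HA1 rose by 1.64 ± 0.11 (adjusted p = 0.015, but adjusted p = 0.090 with an estimated correlation). The 13 clear cell markers had 2 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.046, but adjusted p = 0.090 with an estimated correlation). BRCA2 differed by 0.27 ± 0.13 (adjusted p = 0.117) and BRCA1 by 0.39 ± 0.18 (adjusted p = 0.084), and none of their probe sets was called. In all, limma called 1762 of 17576 genes, 869 higher and 893 lower in PEO4. All 1762 genes past the fold minimum also passed the test, so the fold minimum sets this count; PEO4 minus PEO1 gave 1144 with the mean of all probe sets of a gene. Without PEO1 replicate B, an omission chosen after seeing the data for the lists, 23 interferon-stimulated genes were higher and the hypoxia and glycolysis list reached adjusted p = 0.019 with an estimated correlation. That array lay a median of 0.54 log2 units above the other PEO1 arrays over the interferon-stimulated list and 0.35 over the hypoxia and glycolysis list.

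NCI/ADR-RES is a drug-resistant derivative of OVCAR8, as is known of these lines. ABCB1, which encodes the multidrug efflux pump P-glycoprotein, was at 9.10 ± 0.06 log2 units (SD, n = 3) in NCI/ADR-RES and at 2.51 ± 0.12 in OVCAR8, a rise of 6.59 ± 0.19 (SE), and 6 of its 6 probe sets were called higher. Its neighbour and paralogue ABCB4 rose by 5.90 ± 0.24, with 2 of 3 probe sets called. The presynaptic gene PCLO rose by 6.15 ± 0.27, the pseudogene CTBP2P1 by 5.66 ± 0.25, the lysosomal enzyme GALC by 5.45 ± 0.15, the gap junction gene GJA5 by 4.06 ± 0.22, PTPN7 by 3.96 ± 0.28 and SERPINB7 by 3.91 ± 0.29. The kinase PLK2 fell by 6.59 ± 0.14, keratin KRT6A by 5.90 ± 0.20, complement C3 by 4.87 ± 0.11, the proteoglycan SRGN by 4.04 ± 0.28 and the pseudogene OR7H1P by 5.15 ± 0.17. Pseudogene and paralogue values are uncertain, since probes can be shared with near-identical copies.

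Among chemokines, CXCL8 fell by 4.91 ± 0.16 in NCI/ADR-RES, CXCL5 fell by 4.26 ± 0.22 and CXCL1 fell by 4.06 ± 0.18. Of 20 inflammatory and NF-kB genes 11 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.1e-14, and adjusted p = 3.4e-04 with an estimated correlation). Of 18 antigen presentation genes 3 fell and 0 rose, also adjusted over the list alone, among them HLA-DPA1 by 1.74 ± 0.26 (adjusted p = 0.0044, and adjusted p = 0.0063 with an estimated correlation). Of 32 interferon-stimulated genes 7 fell and 0 rose, also adjusted over the list alone, with IFI27 lower by 3.18 ± 0.16 (adjusted p = 0.047, but adjusted p = 0.298 with an estimated correlation). Without PEO1 replicate B the interferon-stimulated list did not pass at the preset correlation either (adjusted p = 0.072). Of 15 drug and metal transporters, ABCB1 and ABCB4 rose and ABCC3 fell by 1.44 ± 0.16, and the list as a whole did not pass (adjusted p = 0.485). Limma called 868 genes, 439 higher and 429 lower in NCI/ADR-RES. All genes past the fold minimum passed the test here too, and NCI/ADR-RES minus OVCAR8 gave 494 with the mean of all probe sets of a gene.

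**Figure D2:**
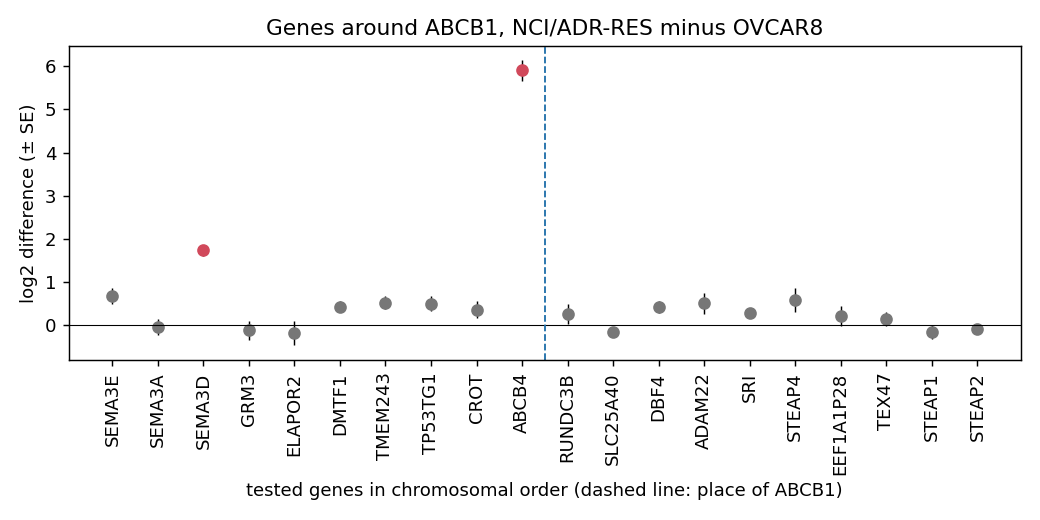
Log2 difference between NCI/ADR-RES and OVCAR8 for the 10 tested genes on each side of ABCB1 in chromosomal order, with SE as bars and called genes in red; the dashed line marks the place of ABCB1. ABCB4 at 5.90 and SEMA3D at 1.74 are called, and the median of the 20 genes is 0.33.

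UWB1.289 carries a BRCA1 mutation and UWB1.289+BRCA1 is its derivative with BRCA1 restored, as is known of these lines. BRCA1 itself did not give 1 direction. Its brightest probe set was at 6.97 ± 0.44 log2 units (SD, n = 3) in arrays labelled UWB1.289+BRCA1 and at 7.58 in the single UWB1.289 array, a difference of -0.62 ± 0.25 (SE) with a limma adjusted p of 0.069. Another BRCA1 probe set differed by -0.89 ± 0.23 and another by 1.94 ± 0.30. Of 10 BRCA1 probe sets, 2 were called higher and 0 lower, and the mean of all probe sets gave 0.34. Which part of the transcript each probe set covers is not given in the sources used here, so BRCA1 does not check the labels.

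**Figure D3:**
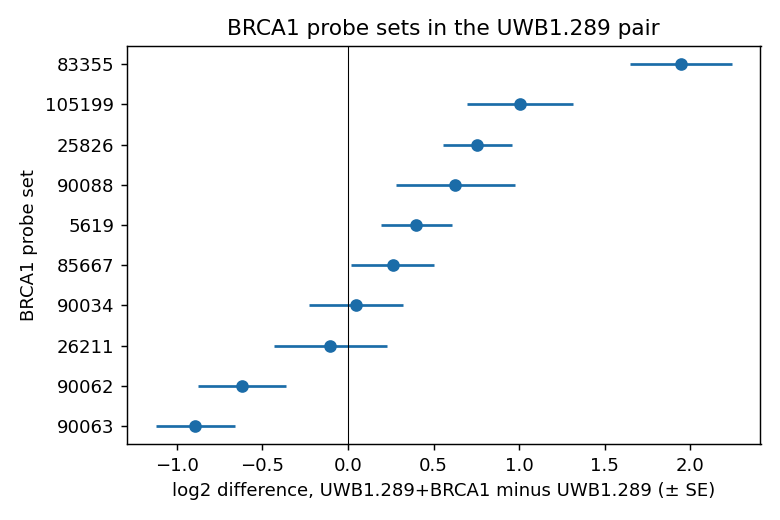
Log2 difference between UWB1.289+BRCA1 (n = 3) and UWB1.289 (n = 1) for each of the 10 BRCA1 probe sets, with SE from the model of all arrays as bars. Differences run from -0.89 to 1.94.

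Mesenchymal genes were lower in UWB1.289+BRCA1 arrays: VIM fell by 4.85 ± 0.36, TGFBI by 2.49 ± 0.43 and SNAI2 by 2.35 ± 0.39, and outside the list the transcription factor TWIST2 fell by 6.32 ± 0.23 and the collagen COL6A1 by 5.18 ± 0.38. The sulfotransferase HS3ST2 fell by 6.95 ± 0.32, the DNA sensor IFI16 fell by 5.82 ± 0.23, TNFSF18 by 5.71 ± 0.39, ARMCX2 by 5.56 ± 0.36, SALL3 by 5.51 ± 0.31 and the growth factor FGF2 by 5.24 ± 0.29. Rises were led by TMEM178A with 6.85 ± 0.40, PASD1 with 6.44 ± 0.25 and the transcriptional coactivator PPARGC1A with 5.42 ± 0.29. ALPK2 rose by 5.16 ± 0.37, CILP by 5.10 ± 0.27, ERP27 by 5.06 ± 0.33, CCBP2 by 4.63 ± 0.22 and KIAA1549L by 4.12 ± 0.24.

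Of 19 mesenchymal genes 10 fell and 0 rose (camera adjusted p = 2.1e-05, and adjusted p = 9.0e-04 with an estimated correlation). Of 21 proliferation genes 10 rose and 0 fell, including TYMS by 1.48 ± 0.10 and MKI67 by 1.31 ± 0.09 (adjusted p = 3.3e-16, and adjusted p = 1.0e-05 with an estimated correlation). Of 20 cholesterol synthesis genes 9 rose and 0 fell, STARD4 by 1.97 ± 0.17 among them (adjusted p = 9.1e-10, and adjusted p = 0.029 with an estimated correlation). Of 19 NRF2 and glutathione genes 9 fell and 0 rose, led by the aldo-keto reductase AKR1C1, which fell by 4.84 ± 0.34 and has near-identical copies that make its identity uncertain (adjusted p = 1.9e-06, and adjusted p = 0.037 with an estimated correlation). Of 37 HOX genes 11 fell and 3 rose (adjusted p = 6.6e-04, and adjusted p = 0.029 with an estimated correlation). Without PEO1 replicate B, an omission chosen after seeing the data, the HOX list had adjusted p = 0.054 with an estimated correlation. For 24 homologous recombination and Fanconi genes 3 rose and 0 fell, FANCD2 by 1.60 ± 0.18 (adjusted p = 6.6e-04, but adjusted p = 0.075 with an estimated correlation). For 32 interferon-stimulated genes 9 fell and 1 rose (adjusted p = 0.0069, but adjusted p = 0.151 with an estimated correlation). Each of these counts was the same when adjusted over the list alone. BRCA2 differed by 0.88 ± 0.19 (adjusted p = 3.9e-04), under the fold minimum, and 1 of its 5 probe sets was called higher. Among the 18 lines, the UWB1.289 array had the lowest proliferation score, -0.88, and the lowest homologous recombination and Fanconi score, -0.48, with UWB1.289+BRCA1 at 0.0027 and -0.07, and the highest NRF2 and glutathione score, 1.14, with UWB1.289+BRCA1 at -0.08. For cholesterol synthesis UWB1.289+BRCA1 was the highest line at 0.85, with UWB1.289 at -0.03. Limma called 1553 genes, 657 higher and 896 lower. The UWB1.289 side is 1 array assumed to vary like the other lines, so the difference cannot be separated from the state of that single sample; UWB1.289+BRCA1 minus UWB1.289 gave 951 with the mean of all probe sets of a gene.

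Histotypes were compared over donors. Between the clear cell donors (n = 2) and the serous donors (n = 5) no gene was called. The genes with the smallest p, given as values, included HENMT1 at 3.03 ± 0.26 log2 units (SD) against 9.85 ± 0.81 and the ion transporter SLC12A7 at 5.28 ± 1.75 against 9.20 ± 0.71, each with a limma adjusted p of 0.089. USP18, an interferon-stimulated gene, was at 3.42 ± 0.20 against 7.85 ± 0.99 (adjusted p = 0.097), CHST15 at 3.26 ± 0.01 against 7.83 ± 0.79 and CMPK2 at 3.63 ± 0.04 against 9.62 ± 0.79. In the other direction BCHE was at 5.03 ± 1.23 against 2.01 ± 0.28, SCN7A at 4.86 ± 0.82 against 2.50 ± 0.16, ACO1 at 9.73 ± 0.05 against 8.16 ± 0.47, LRFN5 2.55 ± 0.45 (SE) higher and POU3F2 at 7.91 ± 3.25 against 4.08 ± 0.13. The 32 interferon-stimulated genes had a median difference of -3.13 and 0 calls, or 4 lower when adjusted over the list alone (camera adjusted p = 2.1e-23, but adjusted p = 0.277 with an estimated correlation). The 24 epithelial genes had a median difference of -1.89 and 0 calls, or 1 lower when adjusted over the list alone (adjusted p = 4.1e-08, but adjusted p = 0.293 with an estimated correlation). The serous markers had a median difference of -1.02 (adjusted p = 0.0037, but adjusted p = 0.547 with an estimated correlation), and the antigen presentation and cholesterol synthesis genes had medians of -0.18 (adjusted p = 0.047, but adjusted p = 0.681 with an estimated correlation) and -0.29 (adjusted p = 0.042, but adjusted p = 0.681 with an estimated correlation). In the other direction, HOX genes had a median of 0.98 (adjusted p = 2.6e-04, but adjusted p = 0.293 with an estimated correlation), p53 targets 0.66 (adjusted p = 0.0011, but adjusted p = 0.547 with an estimated correlation) and proliferation genes 0.21 (adjusted p = 0.0093, but adjusted p = 0.637 with an estimated correlation). These 6 lists had 0 calls, also when adjusted over the list alone. Without PEO1 replicate B, an omission chosen after seeing the data, the cholesterol synthesis list did not pass at the preset correlation either (adjusted p = 0.060). Limma called 0 genes, with 769 of 17576 at an unadjusted p under 0.05, no more than that threshold gives without any difference. Without ES-2 it called 57 and without TOV-21G 86, each then resting on 1 clear cell donor.

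Endometrioid donors (n = 2) were compared with serous donors (n = 5). SNORD114-9, a small nucleolar RNA, was higher in the endometrioid donors, at 5.49 ± 0.43 log2 units (SD) against 1.98 ± 0.10, SNORD113-3 at 4.55 ± 0.09 against 2.27 ± 0.14, SNORD113-1 at 4.44 ± 0.03 against 2.28 ± 0.18 and SNORD114-1 at 4.27 ± 0.22 against 2.25 ± 0.10. SNORD114-17 was higher by 1.69 ± 0.20 (SE), and SNORD114-20 was at 3.32 ± 0.64 (SD) against 1.82 ± 0.10. The long noncoding RNA MEG3 was at 7.38 ± 0.09 against 5.97 ± 0.07, a rise of 1.41 ± 0.12 with a limma adjusted p of 1.8e-04. NTNG2 rose by 2.34 ± 0.26 and KANK1 fell by 5.03 ± 0.61. The 24 epithelial genes had a median difference of -1.84 with 0 calls, also when adjusted over the list alone (camera adjusted p = 2.2e-05, but adjusted p = 0.404 with an estimated correlation). The interferon-stimulated genes had a median of -0.87 (adjusted p = 0.016, but adjusted p = 0.985 with an estimated correlation), HOX genes 0.69 (adjusted p = 7.2e-04, but adjusted p = 0.358 with an estimated correlation), endometrioid markers 0.17 (adjusted p = 0.036, but adjusted p = 0.358 with an estimated correlation) and fibroblast and smooth muscle markers 0.40 (adjusted p = 0.037, but adjusted p = 0.358 with an estimated correlation), each with 0 calls, also when adjusted over the list alone. Without PEO1 replicate B the fibroblast and smooth muscle list did not pass at the preset correlation either (adjusted p = 0.051). Limma called 11 genes, 10 higher and 1 lower. Most serous values of the small RNAs lie near the low end of the array, and the small RNAs have similar copies. Whether the SNORD113, SNORD114 and MEG3 calls are independent of each other was not examined, so they do not count as separate histotype differences. The count was 242 without COV362, when TOV-112D stood alone, and 4 with the stricter filter on dim genes.

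Clear cell against endometrioid donors (n = 2 each) gave 10 called genes, 1 higher and 9 lower in clear cell. KANK1 was higher in clear cell by 5.09 ± 0.73 (SE). SNORD114-9 was lower by 3.47 ± 0.20 at 2.03 ± 0.06 (SD), NTNG2 was at 2.77 ± 0.41 and SNORD113-3 at 2.34 ± 0.05. The same 2 endometrioid donors enter both comparisons, so the calls are not independent. Independence among the small RNA calls was not examined here either. The 14 endometrioid markers had 0 calls, or 1 lower when adjusted over the list alone (camera adjusted p = 0.012, but adjusted p = 0.571 with an estimated correlation). The 32 interferon-stimulated genes had a median difference of -1.79 with 0 calls, or 3 lower when adjusted over the list alone (adjusted p = 1.0e-09, but adjusted p = 0.798 with an estimated correlation). The p53 targets had a median of 0.72 with 0 calls, also when adjusted over the list alone (adjusted p = 0.0015, but adjusted p = 0.798 with an estimated correlation). Without COV362 the count was 185, without ES-2 60, without TOV-21G 79 and without TOV-112D 17.

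A further question was whether lines with the same label resemble each other, which the study addressed with tumour reference libraries that are not analysed here. The 2 endometrioid lines COV362 and TOV-112D correlated at r = -0.266 across gene-centred donor means and the 2 clear cell lines at -0.0447. The serous donors had a mean r of -0.0628 over 10 pairs. Centring each gene over donors tends to make the mean r over all donor pairs negative. A slightly negative r therefore does not by itself show that donors are unlike. Donors of the same class had a mean r of -0.0782 and donors of different classes -0.0658, a difference of -0.0124 (exact permutation test over 756 arrangements, one-sided p = 0.566, n = 9 donors). The within-histotype similarity difference turned to 0.0574 without COV362, with TOV-112D as the only endometrioid donor, and to 0.031 without OV56 (exact permutation p = 0.262). With lines not merged by donor it was 0.056 (permutation p = 0.094). There PEO1 with PEO4 (r = 0.556) and UWB1.289 with UWB1.289+BRCA1 (r = 0.596) count as serous pairs. The permutation also treats these related lines as independent, so that value does not measure resemblance between donors. Of 11 labelled lines, 0 had a nearest unrelated line of its own class. For 4 of them the nearest unrelated line was of a different class. For the other 7 it was a line taken as other, which by this coding could not match. Among these 7 was TOV-21G (clear cell), nearest at r = 0.244 to IGR-OV1, whose mixed label also names clear cell.

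Serous marker scores were 0.53 ± 0.41 (SD, n = 5) in serous donors and -1.08 ± 1.66 (n = 4) in the other classes, with an exact one-sided permutation p of 0.048 that did not pass after adjustment over 3 lists (adjusted p = 0.143). Over omitted donors the serous marker score difference of 1.61 ran from 1.07 without TOV-112D (exact permutation, adjusted p = 0.321) to 2.38 without COV362 (exact permutation, adjusted p = 0.054). COV362, labelled endometrioid, had a serous marker score of 1.20 ± 0.04 (SD, n = 3 arrays), and OVCAR3, whose label names a carcinoma with no histotype, had the highest at 2.33 ± 0.05. Endometrioid markers were high in TOV-112D at 2.08 and not in COV362 at -0.20. The class difference was 1.09 (exact permutation p = 0.111, adjusted p = 0.167). ESR1 entered this score through its brightest probe set, which varied little among the lines. The ESR1 probe set that reached 10.03 in PEO1 was at 6.05 in COV362 and 2.02 in TOV-112D, against the direction of the score. Another was at 2.66 and 3.98, so the score hardly reflects ESR1. Clear cell markers were high in TOV-21G at 1.26 and low in ES-2 at -0.87, with a class difference of 0.09 (exact permutation p = 0.444, adjusted p = 0.444). The smallest p that 2 donors against 7 allow is 0.028. The endometrioid difference was -0.05 without TOV-112D and 2.23 without COV362. The clear cell marker score difference was 1.16 without ES-2, -0.97 without TOV-21G, -0.17 without TOV-112D and -0.07 without PEO1/PEO4.

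**Figure D4:**
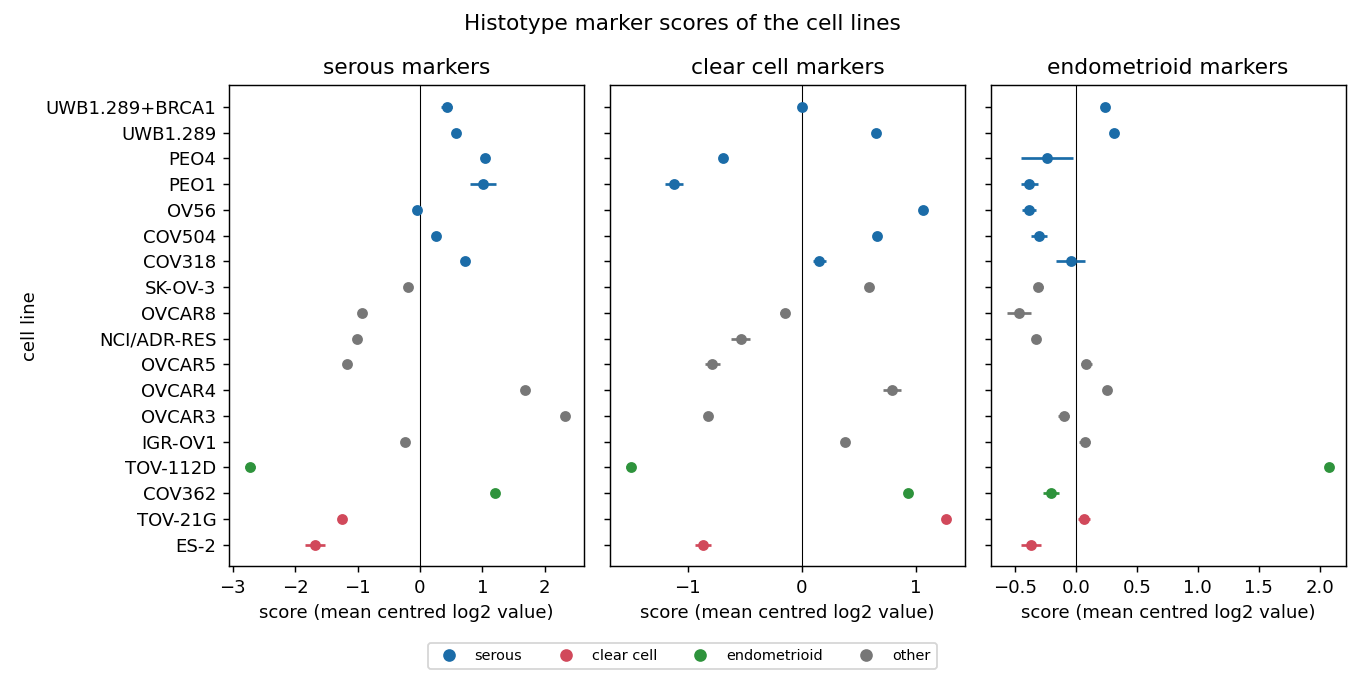
Scores of the 18 lines on the serous, clear cell and endometrioid marker lists, as means of log2 values centred per gene over the 18 lines, with the SD over 3 arrays as bars (UWB1.289 has 1 array). TOV-112D reaches 2.08 on the endometrioid list, where COV362 is at -0.20.

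Epithelial and mesenchymal scores ran against each other over the 15 donors. ES-2 had the lowest epithelial score, -2.06, and the highest mesenchymal score, 1.68, while OVCAR5 had the highest epithelial score, 1.96, with a mesenchymal score of -1.49. COV504 was above 0 on both lists, at 0.88 and 1.02, and TOV-21G below 0 on both, at -1.17 and -0.95. Pearson's r was -0.720 (permutation p = 0.0040) and Spearman's rho -0.761 (permutation p = 0.0016), as the only relation tested in this family. Without OVCAR5 and PEO1/PEO4, the donors farthest from the median epithelial score, r was -0.660.

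**Figure D5:**
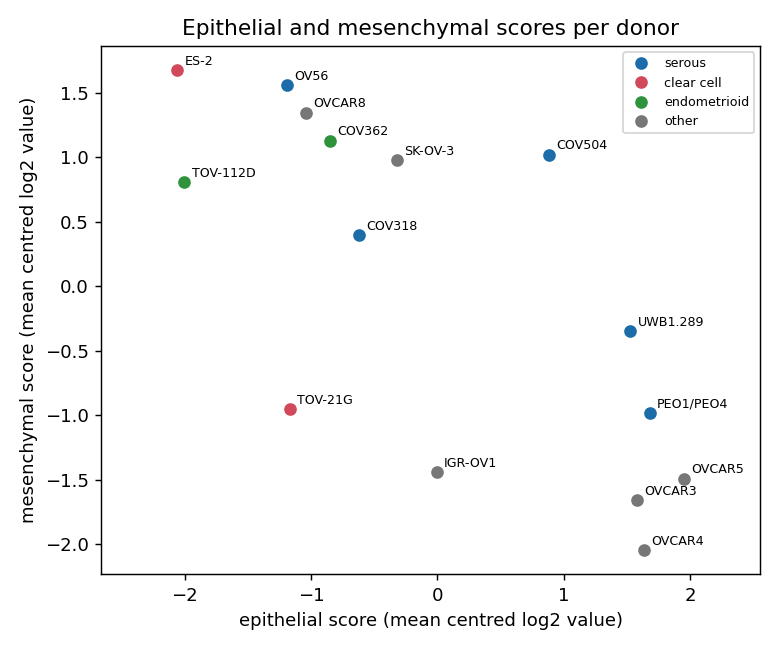
Mesenchymal against epithelial score for each of the 15 donors, as means of log2 values centred per gene over donors, coloured by histotype label. The scores have a Pearson r of -0.720, with COV504 above 0 on both axes.

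Finally, genes high in a single donor were listed. TOV-112D had the most, 97, led by glucagon (GCG) at 13.10 log2 units against 3.26 in the next donor and prolactin (PRL) with a margin of 7.51. The cancer-testis antigen MAGEA4 was at 11.19 in COV504 against 2.38, the pluripotency-associated DPPA4 at 10.29 in COV318 against 3.04, the metalloproteinase MMP3 at 11.05 in ES-2 against 4.62, and the folate receptor FOLR1 at 12.74 in IGR-OV1 against 8.09. Prepronociceptin (PNOC) was at 12.26 in COV362 against 6.62, fibrinogen beta (FGB) at 10.17 in TOV-21G against 5.41, LY6D at 9.52 in OVCAR5 against 3.75, CLEC4E at 10.86 in OV56 against 4.79 and DPP6 at 8.84 in PEO1/PEO4 against 3.70. CT45A5 was at 11.99 in the OVCAR8 donor against 5.28, and belongs to a family of near-identical copies, so its identity is uncertain, as is that of the pseudogene HBBP1, with a margin of 6.77 in ES-2. Limma contrasts called 481 donor-restricted genes in all, down to 6 for the UWB1.289 donor, and 1463 with a margin of 1 log2 unit. Lines of a shared donor were averaged for these contrasts, so a gene high in only 1 of them reached the margin less easily. Counts of such donors, UWB1.289 among them, are therefore not comparable with those of donors with 1 line.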

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

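The tests of PEO1 replicate B against other lines and of its list medians against random lists were chosen after the deviation had been seen. The values here stand far from the rest of their group of donors, by a gap that chance exceeds in about 1 of 20 groups; 8 of 56 values tested did so.

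Among the 5 serous donors, COV504 had a mucinous and intestinal marker score of 0.43, with the next donor at -0.09, and an endothelial marker score of 0.92, with the next at 0.04. The PEO1/PEO4 donor had an ESR1 level of 6.08, with the next at 5.79, in a probe set that varies little where others vary widely. Among the 6 donors taken as other, OVCAR5 had a mucinous and intestinal marker score of 1.68, with the next at -0.08. Its immune cell marker score was 1.06, with the next at 0.01, and its proliferation score was 0.33, with the next at 0.02. WT1 was at 8.11 in OVCAR3, with the next at 5.34. ESR1 was at 5.48 in the OVCAR8 donor, with the next at 5.68, in the same insensitive probe set.

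PEO1 replicate B lay at least 1 log2 unit above the mean of replicates A and C for 1732 genes and below it for 618. Probe sets of the same gene hardly moved together in this deviation, with a correlation of 0.111 over 12530 genes, against 0.730 for PEO4 minus PEO1 and 0.179 for replicate A minus C. The highest correlation of the deviation with another line's difference was 0.111, for COV504. That argues against a full swap with another line in the series, which would make the deviation follow that line's difference. A partial mixture is not excluded, since a deviation whose probe sets hardly moved together could not follow any line closely. Of the 23 lists, 3 had medians above the central 95% of random lists matched on expression: cholesterol synthesis with 0.80 (above 99.95% of them), NRF2 and glutathione with 0.64 (99.91%) and interferon-stimulated with 0.54 (99.46%), while p53 targets at 0.53 and inflammatory and NF-kB genes at 0.48 lay within. Noise of single probe sets may account for the low correlation. By the bound of 4 lists set for it, such noise is not excluded as the whole cause. That bound counts lists and does not weigh how far out they lie, so it cannot settle the question. Those 3 lists leave a shared shift open, and no biological explanation was tested.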

How the results depend on the processing

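Omission of PEO1 replicate B from the gene lists and from results other than PEO4 minus PEO1 was chosen after seeing the data and moved no count of genes or donor pairs by over 1.5 times. Over the lists of all 6 comparisons, it ended the calls of HOX in UWB1.289+BRCA1 minus UWB1.289 (adjusted p = 0.054 with an estimated correlation) and interferon-stimulated in NCI/ADR-RES minus OVCAR8 (0.072, preset), cholesterol synthesis in clear cell minus serous (0.060, preset) and fibroblast and smooth muscle markers in endometrioid minus serous (0.051, preset); in PEO4 minus PEO1 it added HOX (0.038, preset) and hypoxia and glycolysis (0.019, estimated). The cause of the changes below was not tested. With the mean of all probe sets of a gene, calls were 1144 for PEO4 minus PEO1, 494 for NCI/ADR-RES minus OVCAR8, 951 for UWB1.289+BRCA1 minus UWB1.289 and 2 for clear cell minus serous, and BRCA1 turned to 0.34 in the UWB1.289 pair. Without a fold minimum the line pairs gave 6804, 5195 and 4599 calls. The stricter filter left 4 calls in each endometrioid comparison, with fewer genes tested. Lines not merged by donor gave 5 calls for clear cell minus serous and 19 for endometrioid minus serous, and all arrays with line as a random block gave 364, 228 and 113 for the 3 histotype comparisons, where related lines count as separate. Omission of single donors gave 0 to 86 calls for clear cell minus serous, 11 to 242 for endometrioid minus serous and 17 to 185 for clear cell minus endometrioid, which gave 10 without PEO1 replicate B. The similarity difference was 0.056 with lines not merged, where lines of the same donor count as serous pairs. It was 0.011 with Spearman correlation of uncentred means, and ran from -0.0575 to 0.0574 over omitted donors. The clear cell marker difference was -0.31 as a median over the list and ran from -0.97 to 1.16 over omitted donors, and the endometrioid marker difference from -0.0528 to 2.23. A margin of 1 log2 unit gave 1463 donor-restricted genes. Of 31 list calls at the preset correlation, 9 passed with an estimated one. Omission of single arrays gave 1687 to 1994 calls for PEO4 minus PEO1, 868 to 898 for NCI/ADR-RES minus OVCAR8 and 1565 to 1570 for UWB1.289+BRCA1 minus UWB1.289. The replicate block gave 1689 calls for PEO4 minus PEO1, 867 for NCI/ADR-RES minus OVCAR8 and 12885 for genes differing among the 18 lines, fitted without UWB1.289; same-letter arrays did not deviate together (correlations of -0.166 to 0.018), so the letters were not taken to pair samples. Of 234 results for named genes, 148 kept their direction and their side of the thresholds under every alternative run. With the mean of all probe sets of a gene, 62 lost their call and 1 changed direction, more than under any other alternative. Signal near background limits the dim genes, such as the small nucleolar RNAs.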

Other observations

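None of the tests in this part was chosen after its result was seen. OVCAR5 combined the highest mucinous and intestinal marker score of the 18 lines, 1.72, with a PAX8 level of 6.46 in the brightest probe set, though 8.37 in another, and the highest E-cadherin level, 13.25. TOV-112D combined the highest endometrioid marker score, 2.08, with the lowest PAX8 level in either of these probe sets, 3.95 and 4.01. Interferon-stimulated scores were 2.59 in COV318, 1.91 in PEO4, 1.87 in COV362 and 1.75 in COV504, and -1.69 in ES-2 and -1.53 in IGR-OV1. Of 33846 probe sets unnamed here, 12856 (38.0%) were called among the lines.

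Genes beside ABCB1 leaned the same way in NCI/ADR-RES. The 20 neighbours had a median difference of 0.33 log2 units, above 96.8% of 17020 windows of the same size over the genome, and 14 of 20 were above 0. This is consistent with a regional change such as a gain of copies, which the arrays do not measure. Whether ABCB4 reads ABCB1 transcripts through shared sequence cannot be told apart from a rise of its own: 1 neighbour other than ABCB4 (SEMA3D) was called higher, but a regional change and shared sequence can occur together, so that count does not bear on it.

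Differences between related lines ran along the chromosomes. Neighbouring genes correlated at 0.170 for PEO4 minus PEO1, 0.190 for NCI/ADR-RES minus OVCAR8 and 0.149 for UWB1.289+BRCA1 minus UWB1.289, while the highest of 100 shuffled gene orders gave 0.018, 0.020 and 0.024. For differences between replicates A and C of 4 of these lines the values were -0.006 to 0.048, and 3 of the 4 also lay above their own shuffled orders, so a value above the shuffles is not particular to differences between lines. Genes 10 places apart still correlated at 0.094, 0.128 and 0.051. A candidate explanation is divergence in copy number or in regional regulation, which were not tested apart.

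For PEO4 against PEO1 and NCI/ADR-RES against OVCAR8, 10 splits of 6 arrays are too few for a share under 0.05; in each, 1 split, the real one, gave as many calls. The real splits gave 1762 and 868 calls and the highest others 208 and 2. Among 100 regroupings of the 52 arrays, the real one included, 1 gave as many as 13053 called genes, and the highest other gave 214. Regroupings mix arrays of different lines, so few calls were bound to follow. The result shows that arrays of a line resemble each other and does not exclude chance for single genes.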
